A study of Homo sapiens with 36 samples.

How the data were processed

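The unit of the deposited values is the RSEM expected count per gene, per the file headers, and the deposited series matrix holds the same values as the 36 sample files. Per the submitters' processing notes reads were base-called with CASAVA, checked with FastQC, aligned with STAR to GRCh38 (hg38) and quantified with RSEM; versions are not given in the sources used here. All 58721 gene identifiers match GENCODE release 29. Per the series records the H1 cells were grown in E8 medium, differentiated with the WNT activator CHIR99021 and later the WNT inhibitor IWP2, and RNA was taken with NucleoZol for poly(A) libraries read paired-end on a HiSeq. The design text speaks of days 0, 2 and 6 while the sample labels give days 0, 1, 2, 3, 5 and 10, and the labels were used here. How PERK was targeted, which clones were used and whether replicates are separate cultures is not stated.

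Expected counts were rounded to whole numbers, since 6.53% to 9.43% of all gene values per library, zeros included, were fractional. Counts were filtered with filterByExpr (19772 genes kept), scaled with TMM and fitted in edgeR 4.0.16 (limma 3.58.1, R 4.3.3) as 12 groups with 24 residual degrees of freedom, using the quasi-likelihood F test. The common dispersion was 0.0349 (biological coefficient of variation 18.7%). A gene was called at a BH adjusted p under 0.05 within its contrast. Contrasts were PERK KO against wild type at each day, wild type at each later day against day 0, and the genotype-by-day interaction; the wild-type contrasts share the day 0 libraries, so no overlap between them is drawn. These contrasts, the filter, the test, the 29 gene lists and the first set of alternatives were chosen before the data were examined. DESeq2 1.42.0 was an alternative tool, and tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

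Each list of known genes was fixed beforehand (517 of 532 members measured) and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Called lists of 29 by day (0, 1, 2, 3, 5, 10) were 2, 10, 10, 12, 15 and 21 for PERK KO against wild type, 0, 6, 8, 9, 8 and 11 of the same comparisons with an estimated correlation, and 6, 14, 16, 22, 25 and 25 with fry. For wild type against day 0 (days 1, 2, 3, 5, 10) they were 6, 14, 14, 15 and 18, and 6, 7, 8, 9 and 8 with an estimated correlation. The PERK KO calls that held with an estimated correlation at every day from 1 to 10 were pluripotency, cardiac mesoderm and the BMP, NODAL and TGF-beta targets. A gene could be named at a day if it was the targeted gene, was among the 6 largest called changes in each direction (at least 5 CPM in 1 group, without overlap of the libraries), was among the 4 members of a list with the smallest p, was among the 10 strongest interaction genes, or was among the 6 largest genes in each direction called the same way at all days. Folds against a group without counts are lower bounds set with a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% counting interval. Genes that share reads with copies or overlapping genes are left out of the naming where that was known, since their counts are uncertain.

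Library position was the projection of a library on the line between the wild-type means of the previous and the next sampled day. It used genes whose mean log2 CPM differed by at least 1 between those days, with no test of that change. Positions were tested with an exact permutation of the 6 libraries. A self-test used counts simulated from the group means, library sizes and dispersions of the real libraries. Changes were planted at day 3 into genes of at least 1 CPM in wild type (19307 genes, 67 changed 1.5-fold, 67 2-fold and 66 4-fold). Such draws hold no shift of a whole library, so the shares that follow may be too favorable for the real ones. EdgeR on all 36 libraries called 17.9% of 1.5-fold, 64.2% of 2-fold and 100% of 4-fold changes, with 3 false calls (2.42%). DESeq2 called 25.4%, 73.1% and 100% with 17 false calls (11.4%). EdgeR on the 6 libraries alone called 5.97%, 41.8% and 92.4% with 3 false calls (3.12%). Libraries were treated as unpaired.

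Alternatives tried were no filter and a stricter filter, RLE in place of TMM scaling, the series matrix as the source of counts, DESeq2, a fit of only the 6 compared libraries, a replicate block in all groups and within a day, a transcript length offset, camera with an estimated correlation, fry, other gene sets for the time axis, and leaving out each library in turn. After the data were seen a GC content offset and a fit without PERK KO day 0 replicate 2 and wild-type day 2 replicate 3 were added; both libraries differed from the other pair of their groups (chi-square per degree of freedom 163 and 151 against 4.39 for the first, 81.8 and 76.6 against 4.29 for the second). Wild-type day 3 replicates differed in all pairs (26.6, 34.5 and 95.6), with no close pair to set 1 library apart, as did those of wild-type day 10 (26.8, 33.6 and 58.9). Wild-type day 0 replicate 1 also differed from its pair, by less (19.3 and 25.8 against 3.78; 5.20% mitochondrial reads against 7.54% and 8.54%). All of these were kept. Results for 2 genes are not reported here.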

Results

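RNA was sequenced from H1 human embryonic stem cells labeled wild type or PERK KO while the cells were driven toward cardiomyocytes. PERK is a kinase of the endoplasmic reticulum (ER) membrane, encoded by EIF2AK3, that slows translation under ER stress and raises the targets of the transcription factor ATF4. The deposited counts cover 36 libraries, from 2 genotypes at days 0, 1, 2, 3, 5 and 10 with 3 replicates each. The libraries held 14.0 to 25.9 M counted reads (median 18.2 M), and 19772 genes were tested. Nothing in the records says that the replicates are separate cultures, so every p-value below measures only the spread between these samples. PERK KO day 0 replicate 2 stood apart from its group: its counted transcripts averaged 2028 nt, against 2838 and 2783 nt in the other replicates. Wild-type day 2 replicate 3 also differed from the other pair of its group (chi-square per degree of freedom 81.8 and 76.6, against 4.29 between that pair). The wild-type day 3 replicates were spread out (26.6, 34.5 and 95.6 between pairs). Levels are mean CPM ± SD over n = 3 libraries. Log2 fold changes are given ± an approximate SE, the absolute log2 fold change divided by the square root of edgeR's quasi-likelihood F. This SE can understate the error of genes with few counts in a group. P-values of genes carry Benjamini-Hochberg (BH) adjustment. Gene lists were tested with camera at a preset correlation of 0.01, again with BH adjustment, and once more with an estimated correlation.

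**Figure D1:**
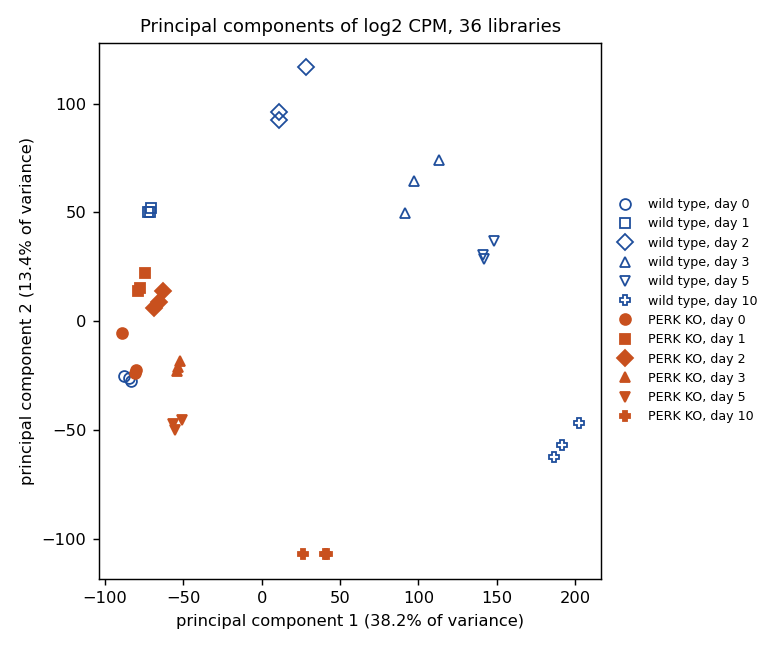
Wild-type libraries moved along the first principal component from day 1 to day 10, while PERK KO libraries of days 0 to 5 stayed at its low end. Each symbol is 1 library, and the axes carry 38.2% and 13.4% of the variance.

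EIF2AK3, the targeted gene (ENSG00000172071.11, GRCh38 chromosome 2, 88556741 to 88627576, minus strand), was counted in all 36 libraries, with 130 to 626 reads each. In wild type it averaged 21.9 ± 3.31 CPM at day 0, 10.7 ± 0.532 at day 1, 16.0 ± 4.43 at day 2, 22.0 ± 5.55 at day 3, 19.9 ± 2.44 at day 5 and 22.1 ± 5.66 at day 10. In PERK KO the same days gave 16.9 ± 4.35, 14.6 ± 0.693, 20.7 ± 1.95, 17.3 ± 0.797, 16.6 ± 0.564 and 22.0 ± 1.06 CPM (SD, n = 3). EIF2AK3 was not called different between the genotypes at any day: log2 fold changes (SE 0.20) were -0.37, 0.45, 0.38, -0.35, -0.27 and -0.01, with edgeR adjusted p = 0.199, 0.133, 0.127, 0.157, 0.25 and 0.981. The edit itself is not described in the records, and gene-level counts cannot show a small edit that leaves the transcript in place. With a GC content offset, chosen after the data were seen, EIF2AK3 was called lower at days 0, 3 and 5 (-0.53, -0.42 and -0.43) and higher at day 1 (0.46).

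**Figure D2:**
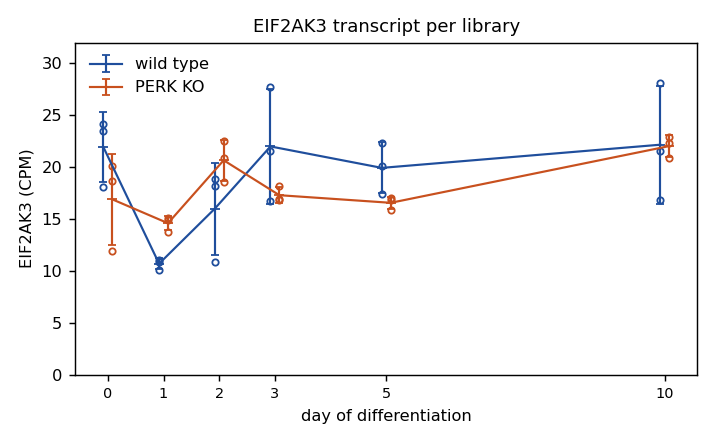
EIF2AK3 transcript in every library by day, with group means and SD. PERK KO libraries kept the transcript at every day.

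Wild-type cells switched on primitive streak genes within 1 day. MIXL1, a homeobox gene of the streak, rose from 1.04 ± 0.167 to 1480 ± 41.8 CPM (log2 fold change 10.45 ± 0.25, n = 3), and TBXT, the T-box factor brachyury, reached 1040 ± 17.0 CPM from 0.11 ± 0.19. EOMES, a T-box factor of mesendoderm, rose by 9.16 ± 0.27. Of 18 measured streak genes 16 were higher and 1 lower (camera adjusted p = 8.6e-62). AXIN2, a feedback inhibitor of WNT signaling, rose by 5.15 ± 0.15, as did 12 of 13 WNT targets (camera adjusted p = 2.73e-51), including SP5, which was raised 8650-fold (95% counting interval 2960 to 41900). SOX2, a pluripotency factor, fell from 257 ± 10.3 to 14.2 ± 3.99 CPM, and PODXL, a surface sialomucin of stem cells, fell by 2.78 ± 0.18. Of 20 pluripotency genes 15 were lower and 1 higher (camera adjusted p = 5.4e-08). CDKN1A, the p53 target that stops the cell cycle, fell by 3.07 ± 0.21. At day 2 the apelin receptor gene APLNR reached 4560 ± 791 CPM from 0.40 ± 0.0516, and 15 of 16 cardiac mesoderm genes were higher (camera adjusted p = 9.34e-34), among them GATA4 at 163 ± 30.6 CPM. TBX6 and DLL3, which pattern presomitic mesoderm, rose by 6.38 ± 0.28 and 5.23 ± 0.21. Targets of the integrated stress response (ISR) were split at day 1, with 10 of 39 higher and 10 lower (camera adjusted p = 0.839), and at day 2 28 were lower and 1 higher (camera adjusted p = 5.06e-10), with STC2, a secreted glycoprotein induced by ATF4, down 4.67 ± 0.21. Adjusted over the list alone these counts were the same except for pluripotency at day 1 (17 lower, 1 higher) and ISR targets at day 1 (11 lower, 11 higher) and day 2 (30 lower, 1 higher). EdgeR called 8819 genes at day 1 (4137 higher, 4682 lower) and 9977 at day 2 (5014 higher, 4963 lower).

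Cardiac genes followed in wild type from day 3. HAND1, a cardiac helix-loop-helix factor, stood at 657 ± 156 CPM at day 3 against 0 counts at day 0, which is at least 9670-fold. Of 18 cardiac transcription factors 13 were higher and 2 lower at day 3 (camera adjusted p = 9.61e-10). ASNS, the asparagine synthetase gene driven by ATF4, fell by 3.08 ± 0.16, with 33 of 39 ISR targets lower and 1 higher (camera adjusted p = 6.76e-13). By day 5 MYH6, the atrial myosin heavy chain, reached 3680 ± 765 CPM from 0.297 ± 0.289, and ACTC1, cardiac actin, 2960 ± 725 from 12.4 ± 2.91. Sarcomere genes were higher in 23 of 25 cases and lower in 2 at day 5 (camera adjusted p = 1.21e-12). PMAIP1, a p53 target that promotes apoptosis, fell by 5.76 ± 0.25. At day 10 TNNI1, slow troponin I, reached 3070 ± 647 CPM (log2 fold change 10.36 ± 0.48) and TPM1, tropomyosin, rose by 3.82 ± 0.15. The fibrillar collagen COL3A1 reached 1700 ± 455 CPM against 0 counts at day 0, at least 26100-fold, and fibronectin FN1 rose by 7.00 ± 0.30. APOA1, an apolipoprotein of endoderm and liver, reached 1020 ± 221 CPM, and 15 of 19 endoderm genes were higher and 2 lower (camera adjusted p = 2.2e-10). SOX2 was down 8.97 ± 0.32 and all 20 pluripotency genes were lower (camera adjusted p = 1.92e-27). PCNA, the replication clamp, fell by 3.98 ± 0.18 beside 18 of 20 S phase genes (camera adjusted p = 5.06e-17), while the hypoxia-inducible growth factor gene VEGFA rose by 4.35 ± 0.14 and SDHA, a subunit of respiratory complex II, by 1.64 ± 0.15. Adjusted over the list alone these counts were unchanged, apart from 1 S phase gene higher. EdgeR called 11233 genes at day 3, 12229 at day 5 and 13678 at day 10. Of the wild-type list calls named here all held with an estimated correlation.

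At day 0, undifferentiated PERK KO and wild-type cells differed most in single genes rather than in whole groups. CTSF, a lysosomal cysteine protease, was nearly absent from PERK KO (0.0801 ± 0.0695 against 14.9 ± 0.857 CPM in wild type; log2 fold change -7.27 ± 0.39, n = 3, edgeR adjusted p = 5.64e-14), and LY6E, a membrane protein induced by interferon, was lower by 5.42 ± 0.49. The zinc finger gene ZNF492 was higher (41.0 ± 4.61 against 3.42 ± 1.03 CPM), as was NHLRC1, an E3 ligase of glycogen metabolism (2.54 ± 0.35). TGFB1, the ligand TGF-beta 1, and SMAD7, an inhibitor in its pathway, were both lower by 0.90. SOX3, a factor of early neural progenitors, was higher by 1.17 ± 0.20, and VIM, the filament protein vimentin, by 1.07 ± 0.14.

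Single stress genes were higher in PERK KO at day 0, while ISR targets as a list were not called. ATF3, a stress-induced repressor downstream of ATF4, was at 41.1 ± 3.49 against 15.5 ± 1.90 CPM (log2 fold change 1.41 ± 0.18), PPP1R15A, which directs the phosphatase that reverses PERK's phosphorylation of eIF2alpha, was higher by 0.79 ± 0.17, and MTHFD2, a mitochondrial folate enzyme, by 0.76 ± 0.14. Of 39 ISR targets 6 were higher and 4 lower (8 and 5 adjusted over the list alone), and the list was not called (camera adjusted p = 0.828). ER chaperones were higher in 8 of 18 cases and lower in none (8 and 0 adjusted over the list alone; camera adjusted p = 0.00624, and adjusted p = 0.522 with an estimated correlation), among them the disulfide isomerase PDIA3 (766 ± 40.4 against 472 ± 38.7 CPM) and HSPA5, the chaperone BiP (851 ± 281 against 438 ± 32.6 CPM). XBP1, the transcription factor of the IRE1 arm, was higher by 1.14 ± 0.19 and SEC61G, a translocon subunit, by 1.86 ± 0.21. Respiratory chain genes were higher in 15 of 28 cases (19 adjusted over the list alone) and lower in none (camera adjusted p = 3.11e-06, and adjusted p = 0.988 with an estimated correlation). Both list calls moved with the short-transcript library, PERK KO day 0 replicate 2: without it they ended (camera adjusted p = 0.0618 for ER chaperones and 0.218 for the respiratory chain). The median log2 fold change went from 0.33 to 0.22 for ER chaperones and from 0.67 to 0.04 for the respiratory chain. EdgeR called 4177 of 19772 genes (2468 higher, 1709 lower; 21.1%), 1322 of them at least 2-fold. With only the 6 compared libraries in the fit 192 genes were called, and PPP1R15A, MTHFD2, PDIA3, HSPA5, XBP1, SEC61G, SOX3, TGFB1, SMAD7 and RIPOR1 lost their calls. A replicate block within the day ended the calls of the same genes and of ATF3, NHLRC1 and VIM (edgeR adjusted p = 0.126, 0.126 and 0.182).

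At day 1, PERK KO cells had more SOX2 and less of the streak and cardiac mesoderm genes. SOX2 stood at 223 ± 27.8 CPM against 14.2 ± 3.99 in wild type (log2 fold change 3.98 ± 0.23, n = 3, edgeR adjusted p = 1.39e-13), and PODXL at 881 ± 35.4 against 204 ± 16.4. HES3, a repressor of the HES family, the ligand gene WNT10B and CUZD1, a CUB-domain gene, were higher by 3.96 ± 0.33, 3.91 ± 0.36 and 4.22 ± 0.38. Pluripotency genes were higher in 7 and lower in 2 of 20 cases (9 and 2 adjusted over the list alone; camera adjusted p = 7.2e-05). MIXL1 reached only 321 ± 31.2 CPM against 1480 ± 41.8 (log2 fold change -2.20 ± 0.17), WNT3, the ligand that opens the streak, 12.4 ± 1.87 against 61.6 ± 3.42, FGF17, a fibroblast growth factor, 6.64 ± 2.97 against 102 ± 20.6, and MESP1, the first cardiac mesoderm factor, 0.421 ± 0.339 against 9.56 ± 2.53. Of 18 streak genes 14 were lower and none higher (17 and 0 adjusted over the list alone; camera adjusted p = 3.02e-30). GATA6, a zinc finger factor of mesendoderm, was at 1.25 ± 0.329 against 81.3 ± 15.8 CPM, APLNR was lower by 3.22 ± 0.21 and GATA4 by 2.77 ± 0.26. Of the cardiac mesoderm genes 12 of 16 were lower (12 lower and 1 higher adjusted over the list alone; camera adjusted p = 3.02e-30). MSGN1 and TBX6, drivers of presomitic mesoderm, were lower by 5.63 ± 0.33 and 2.26 ± 0.23, with 6 of 12 paraxial genes lower (6 adjusted over the list alone; camera adjusted p = 3.63e-11).

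WNT and TGF-beta readouts were lower too at day 1. AXIN2 stood at 263 ± 12.7 against 450 ± 6.77 CPM (log2 fold change -0.78 ± 0.13), the WNT inhibitor DKK1 at 36.3 ± 8.13 against 892 ± 64.0, and LGR5, a receptor that strengthens WNT signals, at 0.195 ± 0.0277 against 7.14 ± 2.44. Of 13 WNT targets 5 were lower and 1 higher (6 and 1 adjusted over the list alone; camera adjusted p = 7.2e-05, and adjusted p = 0.068 with an estimated correlation). CER1, a secreted NODAL and BMP antagonist, was lower by 2.51 ± 0.30 and SMAD7 by 1.39 ± 0.15, beside 9 of 15 BMP, NODAL and TGF-beta targets (11 adjusted over the list alone; camera adjusted p = 2e-11). Of 39 ISR targets 15 were lower and 1 higher (19 and 1 adjusted over the list alone; camera adjusted p = 7.98e-08, and adjusted p = 0.0761 with an estimated correlation). They included PSAT1, the serine synthesis enzyme (308 ± 24.7 against 569 ± 16.6 CPM), WARS, a tRNA synthetase (-1.18 ± 0.15), PPP1R15A (-1.28 ± 0.17) and ATF5, a relative of ATF4 (-1.23 ± 0.18). The ER genes HERPUD1 and CRELD2 were lower by 0.98 ± 0.20 and 0.89 ± 0.21. Of the ER chaperone list 5 of 18 members were lower (7 adjusted over the list alone, camera adjusted p = 0.00605, and adjusted p = 0.17 with an estimated correlation). EdgeR called 3129 genes (1603 higher, 1526 lower; 15.8%), 1440 of them at least 2-fold. The number was 4931 without the 2 libraries that stood apart and 7428 with only the 6 compared libraries.

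**Figure D3:**
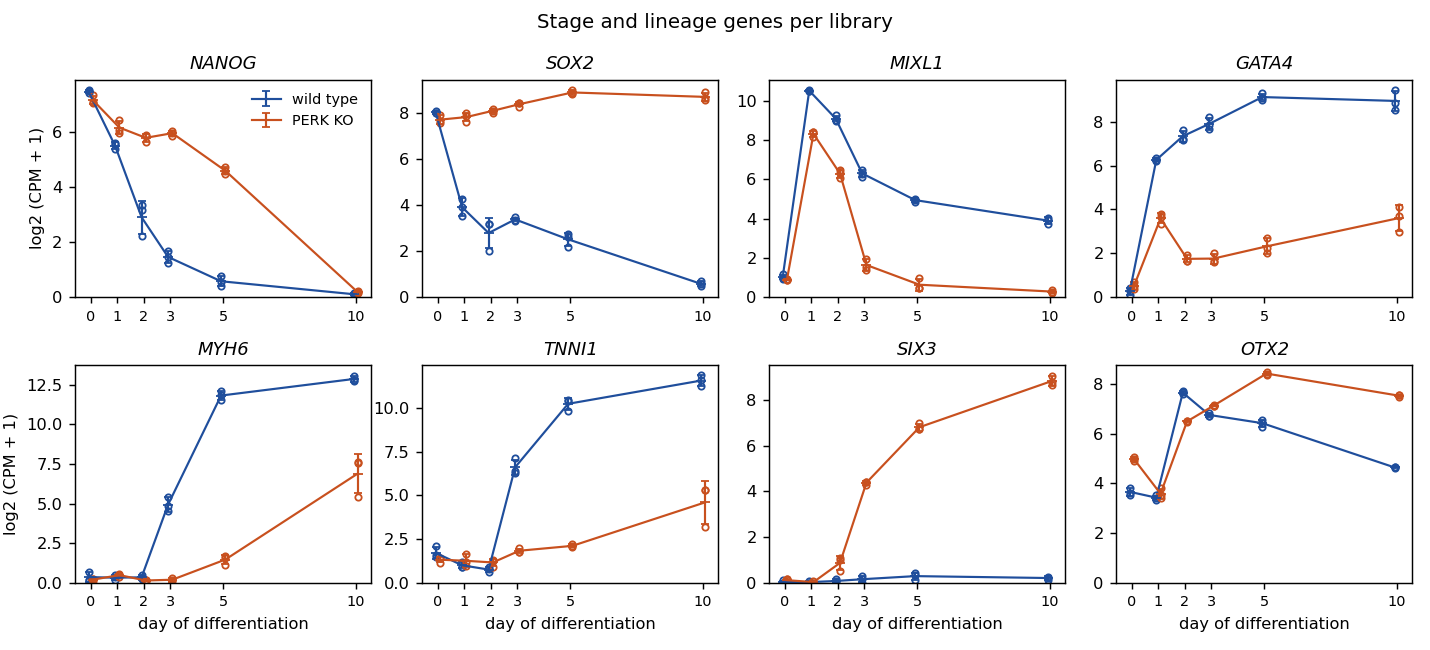
Stage and lineage genes in every library over the days sampled, with group means and SD. NANOG shares reads with a copy, so its level is uncertain.

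At day 2, mesoderm genes were far lower in PERK KO than in wild type. MESP1 stood at 0.835 ± 0.145 against 163 ± 36.7 CPM (log2 fold change -7.59 ± 0.42, n = 3, edgeR adjusted p = 2.49e-15), its neighbor MESP2 at 0.877 ± 0.32 against 244 ± 41.4, and EOMES at 64.0 ± 12.5 against 571 ± 59.3. Of 18 streak genes 15 were lower and 1 higher (16 and 1 adjusted over the list alone; camera adjusted p = 1.69e-23). APLNR was at 57.3 ± 8.92 against 4560 ± 791 CPM, GATA4 at 2.36 ± 0.369 against 163 ± 30.6, and HAND1 at 0.0876 ± 0.0636 against 42.3 ± 10.2, with 14 of 16 cardiac mesoderm genes lower and 1 higher (14 and 1 adjusted over the list alone; camera adjusted p = 8.04e-31). DLL3 was at 20.1 ± 1.96 against 1330 ± 289 CPM and TBX6 was lower by 4.75 ± 0.25. Of 12 paraxial genes 8 were lower and 1 higher (8 and 1 adjusted over the list alone, camera adjusted p = 1.56e-19). FOXC2, a forkhead factor of mesoderm, was 627-fold lower (95% counting interval 214 to 3040), and KCNJ5, a potassium channel gene, 668-fold lower (184 to 5520). Matrix genes were lower as well: LOX, which cross-links collagen, was lower by 7.93 ± 0.38, COL5A1 by 5.00 ± 0.26 and VIM by 2.73 ± 0.15, and 9 of 14 fibroblast genes were lower with 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 1.7e-09). LEF1, a nuclear partner of beta-catenin, was at 8.77 ± 0.285 against 115 ± 1.65 CPM.

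Pluripotency genes were higher in PERK KO than in wild type at day 2. SOX2 was at 269 ± 15.6 against 6.30 ± 2.85 CPM, PODXL at 1250 ± 12.1 against 97.7 ± 9.81, DPPA4, a chromatin protein of early embryos, at 729 ± 19.5 against 214 ± 19.6, and 16 of 20 pluripotency genes were higher with 2 lower (17 and 2 adjusted over the list alone; camera adjusted p = 3.47e-13). APELA, the embryonic ligand of the apelin receptor, was higher by 7.21 ± 0.32, and HPGD, a prostaglandin-degrading enzyme, by 6.73 ± 0.39. ISR targets split, with 10 higher, 12 lower and 17 not called (11 and 13 adjusted over the list alone; camera adjusted p = 0.71): STC2 (2.63 ± 0.20), the lipoprotein receptor VLDLR (2.10 ± 0.15), the mTOR inhibitor DDIT4 (1.81 ± 0.28) and the cystine carrier SLC7A11 (2.25 ± 0.37) were higher. EdgeR called 8427 genes (4127 higher, 4300 lower; 42.6%), 4409 of them at least 2-fold. Of the 10 lists called, cardiac transcription factors and endothelial genes lost the call with an estimated correlation (adjusted p = 0.301 and 0.155 with an estimated correlation).

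At day 3, PERK KO cells held stem cell and early neural genes where wild type held cardiac ones. TDGF1, the NODAL co-receptor of stem cells, stood at 786 ± 12.2 against 44.0 ± 4.07 CPM (log2 fold change 4.16 ± 0.19, n = 3, edgeR adjusted p = 1.05e-17) and SOX2 at 328 ± 20.2 against 9.32 ± 0.592. Of 20 pluripotency genes 16 were higher and 2 lower (16 and 2 adjusted over the list alone; camera adjusted p = 1.45e-19). SIX3, a homeobox gene of the forebrain, was at 19.8 ± 1.24 against 0.114 ± 0.105 CPM, SOX3 at 93.4 ± 8.13 against 1.61 ± 0.558, and ZIC1, a zinc finger factor of neural plate, at 25.2 ± 2.33 against 0.554 ± 0.215. Of 14 neuroectoderm genes 10 were higher and 3 lower (10 and 3 adjusted over the list alone; camera adjusted p = 1.28e-06). HES3 was higher by 7.31 ± 0.42 and IDO1, which degrades tryptophan, by 8.23 ± 0.36. HAND1 was at 1.08 ± 0.284 against 657 ± 156 CPM, GATA4 at 2.41 ± 0.564 against 242 ± 49.5 and APLNR at 18.4 ± 3.03 against 1400 ± 292. All 16 cardiac mesoderm genes were lower (16 adjusted over the list alone; camera adjusted p = 3.66e-33). TBX20, a T-box factor of the heart, was 827-fold lower (95% counting interval 283 to 4010), TBX2 1360-fold lower (375 to 11200), and INSRR, an insulin receptor relative, 1310-fold lower (448 to 6350). Cardiac transcription factors were lower in 15 of 18 cases and higher in 2 (15 and 2 adjusted over the list alone; camera adjusted p = 3.15e-11). The early sarcomere genes MYL4 and MYH6 were lower by 8.53 ± 0.56 and 7.65 ± 0.56.

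Matrix and sterol genes were lower at day 3, and single ISR targets differed. VIM was at 209 ± 16.7 against 3780 ± 875 CPM and the collagen gene COL1A2 at 69.8 ± 2.55 against 1190 ± 131, with 10 of 14 fibroblast genes lower (11 lower and 1 higher adjusted over the list alone; camera adjusted p = 6.45e-13). Of 20 cholesterol genes 18 were lower and none higher (19 and 0 adjusted over the list alone; camera adjusted p = 2.78e-05), with SREBF2, the transcription factor that drives sterol synthesis, lower by 1.07 ± 0.14. ISR targets again split, 15 higher and 6 lower of 39 (16 and 6 adjusted over the list alone; camera adjusted p = 0.114): PSAT1 (1.09 ± 0.10), ATF3 (1.48 ± 0.19) and STC2 (2.59 ± 0.20) were higher, PPP1R15A lower (-1.49 ± 0.17). HSPA5 was lower by 0.79 ± 0.18. MCM6, a subunit of the replicative helicase, was higher by 1.45 ± 0.10 beside 13 of 20 S phase genes, with 2 lower (15 and 2 adjusted over the list alone; camera adjusted p = 0.0158, and adjusted p = 0.499 with an estimated correlation). NDRG1, a stress-responsive gene of differentiating cells, had 0 counts in PERK KO at day 3, at least 467-fold below wild type. EdgeR called 8922 genes (4332 higher, 4590 lower; 45.1%), 5369 of them at least 2-fold. Among the 12 lists called, the S phase call ended without wild-type day 3 replicate 1 (camera adjusted p = 0.057), and sarcomere genes and WNT targets lost theirs with an estimated correlation (adjusted p = 0.492 and 0.299 with an estimated correlation).

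At day 5, sarcomere genes were higher in wild type and neuroectoderm genes were higher in PERK KO. MYH6 stood at 1.79 ± 0.537 CPM in PERK KO against 3680 ± 765 (log2 fold change -11.01 ± 0.51, n = 3, edgeR adjusted p = 1.19e-17), ACTC1 at 24.2 ± 0.996 against 2960 ± 725, TNNI1 at 3.31 ± 0.235 against 1230 ± 274 and the myosin chaperone UNC45B at 0.309 ± 0.149 against 230 ± 21.3. Of 25 sarcomere genes 22 were lower and 1 higher (22 and 1 adjusted over the list alone; camera adjusted p = 1.47e-11, and adjusted p = 0.0502 with an estimated correlation). HAND2, a helix-loop-helix factor of the heart, was lower by 11.42 ± 0.68 and GATA4 by 7.10 ± 0.32, and SMYD1, a muscle histone methyltransferase, had a log2 fold change of -10.81 ± 0.59. Cardiac transcription factors were lower in 16 of 18 cases and higher in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 5.42e-15). On the other side, SIX3 reached 111 ± 12.5 against 0.225 ± 0.124 CPM, the forebrain factors LHX5 and FEZF1 118 ± 7.75 and 142 ± 15.1 against 0.11 ± 0.14 and 0.163 ± 0.0282, and ZIC1 60.4 ± 1.74 against 0.137 ± 0.138. OTX2, which marks fore- and midbrain, was higher by 2.01 ± 0.11 and OLIG3, a helix-loop-helix factor of the dorsal neural tube, 680-fold (95% counting interval 188 to 5620). Of 14 neuroectoderm genes 9 were higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 1.71e-08). SOX2 was at 468 ± 36.5 against 4.74 ± 1.06 CPM and DNMT3B, the de novo DNA methyltransferase of stem cells, at 1150 ± 59.4 against 113 ± 12.1, and 19 of 20 pluripotency genes were higher with 1 lower (19 and 1 adjusted over the list alone; camera adjusted p = 4.84e-20).

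Metabolic and matrix genes separated the genotypes at day 5 as well. PDK1, a kinase that inhibits pyruvate dehydrogenase, was at 47.3 ± 3.91 against 534 ± 98.7 CPM, PFKP, a phosphofructokinase, was lower by 2.60 ± 0.14 and SLC16A3, a lactate exporter, by 4.32 ± 0.23. Of 25 glycolysis and hypoxia genes 17 were lower and 3 higher (18 and 4 adjusted over the list alone; camera adjusted p = 2.43e-06, and adjusted p = 0.21 with an estimated correlation). FN1 was at 105 ± 19.7 against 5750 ± 502 CPM, and 12 of 14 fibroblast genes were lower (12 adjusted over the list alone; camera adjusted p = 5.87e-12). MVK, mevalonate kinase, was lower by 2.78 ± 0.23 with 19 of 20 cholesterol genes (19 adjusted over the list alone; camera adjusted p = 2.83e-07). BUB1, a spindle checkpoint kinase, was higher by 1.73 ± 0.19, as were 12 of 22 G2 and M phase genes with 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 0.0119, and adjusted p = 0.182 with an estimated correlation). Of 39 ISR targets 15 were higher and 9 lower (15 and 9 adjusted over the list alone; camera adjusted p = 0.334): PSAT1 (1.63 ± 0.10) and SLC7A11 (4.03 ± 0.43) were higher, PPP1R15A (-2.13 ± 0.17) and VLDLR (-2.42 ± 0.15) lower. EdgeR called 11675 genes (5647 higher, 6028 lower; 59.0%), 7276 of them at least 2-fold. The paraxial call of day 5 (7 lower and 1 higher of 12, also when adjusted over the list alone; camera adjusted p = 0.0485, and adjusted p = 0.239 with an estimated correlation) ended when any 1 of 5 libraries was left out (camera adjusted p up to 0.0635) and with the GC content offset (0.19).

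**Figure D4:**
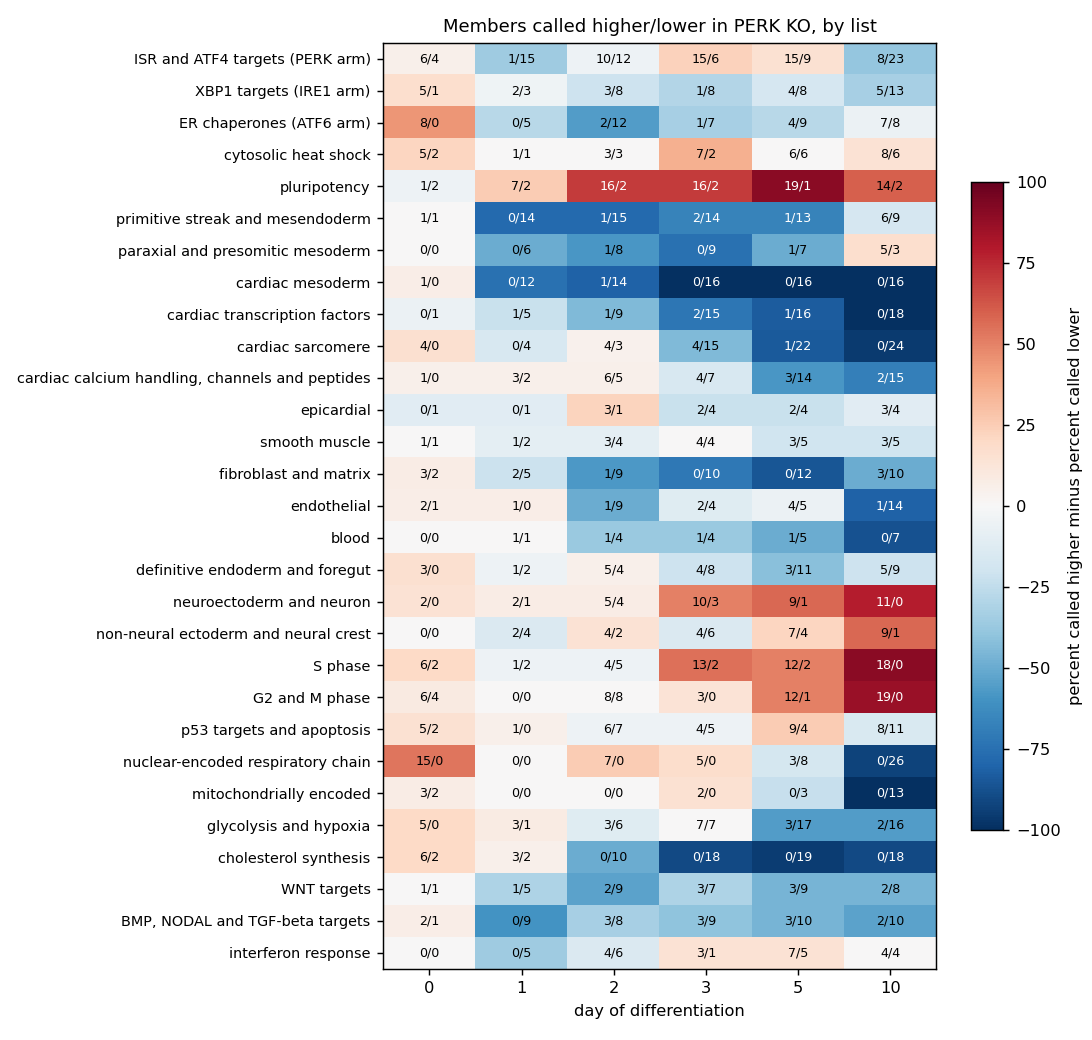
Members of each fixed list called higher and lower in PERK KO, by day. The color is the percentage called higher minus the percentage called lower.

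At day 10, PERK KO cells expressed neural and surface ectoderm genes, and contractile genes stood far below wild type. SIX3 reached 455 ± 67.4 CPM against 0.153 ± 0.0577 in wild type (log2 fold change 11.54 ± 0.39, n = 3, edgeR adjusted p = 1.54e-20), OTX2 184 ± 5.88 against 23.9 ± 0.483 and MAP2, a microtubule protein of neurons, 145 ± 27.1 against 0.964 ± 0.0366. PAX6, a paired-box factor of eye and forebrain, was 1940-fold higher (95% counting interval 664 to 9420), RAX, a retinal homeobox gene, 10400-fold (1860 to 410000), LHX5 4440-fold (797 to 175000) and CYP26C1, which degrades retinoic acid, 2990-fold (827 to 24700). Of 14 neuroectoderm genes 11 were higher and none lower (11 and 0 adjusted over the list alone; camera adjusted p = 4.12e-11). GRHL2 and TFAP2C, factors of surface ectoderm, were higher by 5.61 ± 0.29 and 5.78 ± 0.33, DLX5, a homeobox gene of the neural plate border, by 7.22 ± 0.38, and SOX10, a neural crest factor, by 3.86 ± 0.30, with 9 of 14 non-neural ectoderm and crest genes higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.000108). LIN28A, an RNA-binding protein of stem cells, was at 1310 ± 7.48 against 187 ± 29.2 CPM and SOX2 at 411 ± 53.6 against 0.497 ± 0.12. DPPA4 was higher by 2.08 ± 0.10, while TDGF1 was lower by 3.04 ± 0.20. Of 20 pluripotency genes 14 were higher and 2 lower (14 and 3 adjusted over the list alone, camera adjusted p = 9.13e-07). These are differences from wild type of the same day, and do not show that PERK KO cells stayed pluripotent.

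Sarcomere and calcium handling genes were low in PERK KO at day 10. TNNI1 stood at 28.3 ± 17.5 against 3070 ± 647 CPM, TPM1 at 415 ± 6.93 against 3030 ± 325 and ACTN2, the Z-disc actinin, at 10.5 ± 4.85 against 314 ± 23.7. In total 24 of 25 sarcomere genes were lower (24 adjusted over the list alone; camera adjusted p = 1.12e-11). GATA4 was lower by 5.44 ± 0.29 and IRX4, a ventricular homeobox gene, by 7.34 ± 0.38, as were all 18 cardiac transcription factors (18 adjusted over the list alone; camera adjusted p = 2.85e-13). HRC, a calcium-binding protein of the sarcoplasmic reticulum, was lower by 4.60 ± 0.20, the pacemaker channel gene HCN4 by 5.35 ± 0.29 and RRAD, a small GTPase that restrains calcium channels, by 9.05 ± 0.41. Of 19 calcium handling genes 15 were lower and 2 higher (15 and 2 adjusted over the list alone; camera adjusted p = 4.16e-08). COL3A1 was at 5.45 ± 2.66 against 1700 ± 455 CPM and C7, a complement component of stroma, was lower by 9.03 ± 0.42, but VWF, the endothelial clotting factor, was higher by 2.90 ± 0.23 while 14 of 16 endothelial genes were lower and 1 higher (14 and 1 adjusted over the list alone; camera adjusted p = 0.00174, and adjusted p = 0.0536 with an estimated correlation). The endoderm genes APOA1 and FOXA2 were lower by 3.31 ± 0.30 and 3.75 ± 0.24. ER chaperones (7 of 18 higher, 8 lower, camera adjusted p = 0.938) were not called, nor were epicardial, smooth muscle, endoderm, p53, heat shock, interferon and paraxial lists.

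Cell cycle, mitochondrial, sterol and ISR genes differed at day 10 as well. PCNA was at 84.0 ± 6.80 against 13.3 ± 2.64 CPM and MCM6 higher by 1.69 ± 0.10, with 18 of 20 S phase genes higher and none lower (18 and 0 adjusted over the list alone; camera adjusted p = 1.07e-09). BUB1B, a spindle checkpoint kinase, and TPX2, a spindle assembly factor, were higher by 2.76 ± 0.19 and 1.13 ± 0.10, with 19 of 22 G2 and M phase genes (19 adjusted over the list alone; camera adjusted p = 2.62e-07). SDHA was at 41.6 ± 2.37 against 337 ± 47.8 CPM and ATP5F1A, a subunit of ATP synthase, lower by 1.65 ± 0.14, and 26 of 28 respiratory chain genes were lower (27 adjusted over the list alone; camera adjusted p = 1.27e-06, and adjusted p = 0.28 with an estimated correlation). The mitochondrial transcripts MT-CO3 and MT-ND4 were lower by 1.40 ± 0.13 and 1.58 ± 0.17, with all 13 mitochondrial genes lower (13 adjusted over the list alone; camera adjusted p = 7.79e-05, and adjusted p = 0.245 with an estimated correlation), and mitochondrial reads made up 2.90% of PERK KO and 5.36% of wild-type counts. INSIG1, the sterol sensor partner, was lower by 3.55 ± 0.19 and SQLE, squalene epoxidase, by 1.97 ± 0.11, beside 18 of 20 cholesterol genes (19 adjusted over the list alone; camera adjusted p = 3.55e-09). VEGFA was lower by 2.26 ± 0.12. Of 39 ISR targets 23 were lower and 8 higher (23 and 8 adjusted over the list alone; camera adjusted p = 0.0442, and adjusted p = 0.45 with an estimated correlation): PPP1R15A was at 37.7 ± 3.16 against 214 ± 70.3 CPM and ATF3 lower by 2.96 ± 0.19, while PSAT1 was higher by 1.69 ± 0.10. EdgeR called 13301 genes (6575 higher, 6726 lower; 67.3%), 9012 of them at least 2-fold. The ISR call ended without wild-type day 10 replicate 2 or without PERK KO day 10 replicate 3 (camera adjusted p up to 0.0621) and with the GC content offset (0.271), and this day had the largest difference in GC trend between the genotypes (0.399 log2 units per 10 points of GC in wild type, -0.277 in PERK KO).

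Across the days, most genes changed their PERK KO effect. ENC1, an actin-binding BTB protein, was lower at day 1 (-2.40 ± 0.17) and day 3 (-4.61 ± 0.18) and higher at day 10 (3.75 ± 0.17). TPBG, the trophoblast glycoprotein, was higher by 5.14 ± 0.14 at day 10. SFRP2, a secreted WNT modulator, was higher by 2.90 ± 0.18 at day 3, 4.66 ± 0.20 at day 5 and 9.20 ± 0.26 at day 10, and ZIC2, a neural zinc finger factor, by 2.47 ± 0.14, 4.20 ± 0.15 and 4.76 ± 0.15. COL2A1, the cartilage collagen, was lower at days 3 and 5 (-6.47 ± 0.24 and -8.08 ± 0.25), BMPER, a BMP modulator, at days 3 and 10 (-7.84 ± 0.23 and -4.43 ± 0.19), and SCUBE1, a secreted EGF-domain protein, turned from lower at day 5 (-4.15 ± 0.18) to higher at day 10 (4.46 ± 0.17). UAP1L1, a nucleotide sugar enzyme, went the other way, from 3.48 ± 0.19 at day 3 to -6.40 ± 0.22 at day 10, as did VAT1L, a synaptic vesicle protein relative (4.61 ± 0.15 at day 3, lower at day 10). The edgeR interaction of genotype and day was called for 15988 of 19772 genes (80.9%). Whether the PERK KO cells of all days came from 1 stock is not recorded. A difference between stocks was not separated from one between days. Only 81 genes were called the same way at all 6 days, 30 higher and 51 lower, against 1.56 for independent days. The count was 53 without a filter, 130 without PERK KO day 0 replicate 2 and 149 without the 2 libraries that stood apart. Among them SOX3 (1.17 to 5.86) and ZNF492 were higher, and CTSF, TGFB1 (-0.90 at day 0 to -5.76 at day 5), SMAD7 (-0.90 at day 0 to -3.59 at day 10) and RIPOR1, a RHOA inhibitor (-1.01 at day 0 to -3.54 at day 2), were lower.

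**Figure D5:**
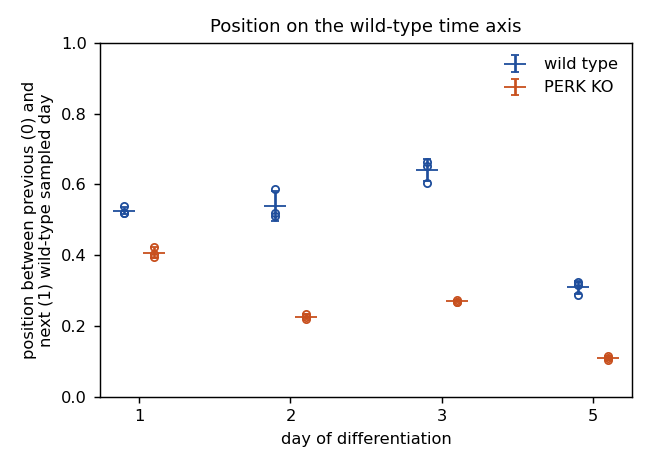
Position of each library between the wild-type days before and after its own, with group means and SD. PERK KO libraries sat lower than wild type at days 1, 2, 3 and 5.

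PERK KO libraries of days 1, 2, 3 and 5 had lower positions on the wild-type time axis than wild-type libraries of the same day. On an axis from the previous (0) to the next (1) sampled wild-type day, wild type stood at 0.526 ± 0.010 and PERK KO at 0.408 ± 0.015 at day 1 (6794 genes). The pair was 0.538 ± 0.041 and 0.226 ± 0.007 at day 2 (7319 genes), 0.640 ± 0.031 and 0.269 ± 0.003 at day 3 (5498 genes), and 0.309 ± 0.019 and 0.109 ± 0.006 at day 5 (7176 genes). The exact permutation test gave p = 0.1 at each day (n = 3), the smallest value that 20 relabelings allow. By correlation the closest wild-type day of PERK KO day 1 was its own day; it was day 1 for PERK KO of day 2, and day 0 for PERK KO of days 3 and 5. At day 10 the PERK KO libraries were close to no wild-type day (r = 0.30, 0.20 and 0.30 with days 10, 0 and 10).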

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

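The tests on the neuroectoderm genes and on PERK KO day 0 replicate 2 were chosen after the result was seen, while the interaction, the exchanges of genotypes and the splits of libraries were planned before. The interaction of genotype and day was called for 15988 genes, against at most 13301 genes at a single day and 17921 called at any day. The interaction tests all days together, so its count is not like that of a single day. Its 10 strongest named genes were ENC1, TPBG and ZIC2 (edgeR adjusted p = 5.9e-21 each), SCUBE1, VIM, SFRP2, COL2A1 and BMPER (1.77e-20 each), and VAT1L and UAP1L1 (1.91e-20 each). When genotypes were exchanged at random within days, 1 of 40 exchanges, the real one, gave as many interaction calls, and the highest other gave 7102. The 81 genes changed the same way at all 6 days were matched by 1 of 40 exchanges, again the real one, and the highest other gave 0. An exchange that mixes the genotypes at any 1 day leaves few or no calls there, so 0 was close to certain beforehand. The exchanges break up the genotype effect itself. Neither count therefore tests whether that effect is shared by the days or differs between them.

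Neuroectoderm genes were higher in PERK KO at day 10, and of 3 other readings a delayed wild-type course predicts levels no higher than some wild-type day, but 8 of the 11 members called higher stood above every wild-type library, with SIX3 10.78 and MAP2 5.24 log2 units over the highest wild-type day. The median of 1.67 describes only these 11, which were picked for being higher at day 10, and OTX2 (-0.12), ELAVL3 (-1.08) and TUBB3 (-2.47) lay below that day. A lower share of cardiac cells predicts that genes of all other cell types rise alike, but the 76 members of the 6 lists of other types had a median log2 fold change of -1.96. In wild type at day 10 the fibroblast, endothelial, blood and endoderm lists were themselves called higher at the preset correlation, the epicardial and smooth muscle lists not. Such genes can be lost together with cardiac ones, so their fall does not decide against a lower cardiac share. It shows only that not all other types rose. Non-neural ectoderm and crest genes, outside those lists, rose too (9 of 14 higher). A GC content trend predicts that the change shrinks once the trend is removed, but the median of the list with the offset was 4.06. For OTX2, ELAVL3 and TUBB3 a delayed course may still be enough. A change of fate, outgrowth of another population and a difference between clones or stocks were not tested and stay open.

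PERK KO day 0 replicate 2 carried short transcripts, and 2 results of day 0 were tried without it. Without it 4545 genes were called, 2873 of them among the 4177; leaving out a differing library also changes the spread, so this count does not decide how many calls rest on it. The respiratory chain median log2 fold change went from 0.67 to 0.04 (camera adjusted p = 0.218 without the library), and ER chaperones from 0.33 to 0.22 (0.0618). The higher respiratory chain at day 0 is therefore likely a property of this 1 library and not of PERK KO, while for ER chaperones this stays open.

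Whether any grouping of the 6 libraries of a comparison would give such counts was tried by counting calls over all 10 splits into 3 and 3. For called genes at each of the 6 days of PERK KO against wild type and each of the 5 wild-type contrasts, 1 of 10 splits, the real one, gave as many calls, and all other splits gave 0; 10 splits cannot give a share under 0.05. For gene lists at the preset correlation other splits came close: the real split gave 2, 13, 13, 12, 14 and 18 called lists in PERK KO at days 0, 1, 2, 3, 5 and 10, and the highest other split 4, 11, 9, 12, 13 and 17. As many lists as in the real split were called in 4, 1, 1, 2, 1 and 1 of 10 splits. In the wild-type contrasts at days 1, 2, 3, 5 and 10 the real split gave 9, 11, 11, 14 and 15 lists, the highest other 11, 13, 12, 13 and 20, and 2, 3, 4, 1 and 4 of 10 splits gave as many. Every other split still sets 2 libraries of 1 group against 1, so it carries part of the real difference, and these list counts do not decide.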

How the results depend on the processing

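The GC content offset and the fit without the 2 libraries that stood apart were chosen after seeing the data; all other alternatives were fixed beforehand. No called result reversed its direction under any alternative. Of 3542 values for the 210 named gene results, 3519 kept their call, and the others lost it at day 0 with only the 6 libraries or with the replicate block within the day. The 210 values with the series matrix as the source could not differ, since it holds the same counts. Of 2262 values for the 174 list results, called or not, 2072 kept their direction and their side of the threshold. Over all alternatives the genes called in PERK KO ranged from 7948 to 10623 at day 3, 10532 to 13546 at day 5 and 12342 to 14451 at day 10, the interaction from 15089 to 17050 genes, and the shift of PERK KO on the time axis from -0.174 to -0.111 at day 1, -0.326 to -0.262 at day 2, -0.388 to -0.352 at day 3 and -0.215 to -0.193 at day 5. At day 0 the 4177 called genes became 192 with only the 6 libraries compared. At day 1 the 3129 became 7428 with only the 6 libraries and 4931 without the 2 libraries. Fewer degrees of freedom are left in every fit of 6 libraries, also where calls rose, so this alone does not account for the fall. Such a fit takes its spread from that comparison only, which at day 0 includes PERK KO replicate 2. The 2 libraries left out are not from day 1, so they act there only through what the fit shares. Which shared part did so, and why 6 libraries gave more calls, was not tested. The 81 genes changed the same way at all 6 days became 53 without a filter and 149 without the 2 libraries, and leaving out 1 library at a time gave 54 to 130. EIF2AK3, not called in the report, was called with the GC content offset at day 0 (-0.53), day 1 (0.46), day 3 (-0.42) and day 5 (-0.43), and without the 2 libraries at day 1 (0.46); the cause was not tested. Its uncalled value changed sign with the length offset at day 5 (0.07), and at day 10 it was 0 without a filter, 0.05 with the stricter filter, 0.05 with the length offset and 0.01 without the 2 libraries. Leaving out 1 library at a time it ranged from -0.51 to -0.14 at day 3, called without wild-type day 3 replicate 3, and from -0.16 to 0.20 at day 10. Gene lists called fell with an estimated correlation to 0 at day 0, 6 at day 1, 8 at day 5 and 11 at day 10, and rose with fry to 6 at day 0, 16 at day 2, 22 at day 3 and 25 at day 5; at day 0 they fell to 0 without the 2 libraries and ranged from 0 to 3 with 1 library left out. The split of higher against lower calls moved by less than 10 percentage points under every scaling. In the day 3 self-test on simulated counts 17.9% of 1.5-fold changes were called. That test changed few genes, while 8922 were called in the real day 3 comparison, which eases the adjusted threshold. Its share is therefore no measure of how many small changes were missed here. How far depth limits the calls of weakly expressed genes was not tested.

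The replicate numbers gave no pairing: same-numbered libraries of the 2 genotypes deviated together with correlations from -0.11 to 0.25. With a replicate block within the day the called genes were 10 at day 0, 7382 at day 1 and 5396 at day 2, and with a replicate block over all libraries EIF2AK3 at day 10 was 0.01.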

Other observations

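The list tests in this part were fixed beforehand, and the tests on NDRG1, ST3GAL1 and ZFP41 were chosen after the result was seen. XBP1 targets, genes of the IRE1 arm, were lower in 13 and higher in 5 of 24 cases in PERK KO at day 10 (13 and 5 adjusted over the list alone; camera adjusted p = 0.0484, and adjusted p = 0.0829 with an estimated correlation), a call that ended when any 1 of 4 libraries was left out (camera adjusted p up to 0.0793). Interferon genes were lower in 5 of 14 cases at day 1 (5 adjusted over the list alone; camera adjusted p = 0.000792). Blood genes were lower in 4 and higher in 1 of 8 cases at day 2 (5 and 1 adjusted over the list alone; camera adjusted p = 0.00752), and in 7 of 8 at day 10 (7 adjusted over the list alone; camera adjusted p = 0.0157, and adjusted p = 0.0726 with an estimated correlation).

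Streak genes were still lower in 9 and higher in 6 of 18 cases at day 10 (9 and 6 adjusted over the list alone; camera adjusted p = 0.0151, and adjusted p = 0.28 with an estimated correlation), a call that ended with the GC content offset (0.0734). BMP, NODAL and TGF-beta targets were lower in 10 and higher in 2 of 15 cases at day 10 (10 and 2 adjusted over the list alone; camera adjusted p = 0.000373). Wild-type p53 targets fell from day 0, with 13 of 20 lower and 1 higher at day 1 (15 and 1 adjusted over the list alone; camera adjusted p = 0.000843) and 18 lower and 2 higher at day 5 (18 and 2 adjusted over the list alone; camera adjusted p = 8.86e-07). By day 10 the list was no longer called, with 12 lower and 4 higher (camera adjusted p = 0.114, and adjusted p = 0.264 with an estimated correlation). Glycolysis and hypoxia genes of wild type rose in 21 of 25 cases by day 10 and fell in 2 (21 and 2 adjusted over the list alone; camera adjusted p = 4.53e-08, and adjusted p = 0.118 with an estimated correlation).

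NDRG1, ST3GAL1 and ZFP41 on chromosome 8 were almost without counts in PERK KO at days 3 and 5 only. Summed over 3 libraries NDRG1 had 304, 99, 125, 0, 2 and 2180 counts at days 0, 1, 2, 3, 5 and 10, ST3GAL1 340, 197, 240, 0, 3 and 316, and ZFP41 171, 408, 427, 0, 2 and 495. Low depth is excluded, as the smallest expected count was 98.3, and 1 deletion spanning all 3 genes is excluded, as 14 of the 14 expressed genes between them, other than ST3GAL1, kept at least 50% of their lowest level at the other PERK KO days. A separate culture or clone of PERK KO cells at days 3 and 5 stays possible. At this pair of days 5 genes were lost, and at most 1 at each of the other 14 pairs. That count cannot decide, since the pair was picked for the loss of these 3 genes, which can be among the 5. The pair is also set apart by its days. The flanking genes PHF20L1 (1124 and 1945 counts) and ZFAT (485 and 414) kept their counts at days 3 and 5, and a short deletion from NDRG1 to ST3GAL1 with a separate event at ZFP41 was not tested.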
